A study of Rattus norvegicus with 6 samples.

How the data were processed

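Gene expression was measured by RNA sequencing in primary hippocampal neuron cultures of embryonic day 17 Wistar rats, an outbred laboratory strain. Per the labels' protocols, cytosine arabinoside, which limits the growth of dividing non-neuronal cells, was added at 10 µM on day 3, and cultures were used after 12 days in vitro. Palmitic acid, a saturated fatty acid, was given at 200 µM on a bovine serum albumin carrier to 3 cultures, and 3 cultures received vehicle. The duration of exposure is not given in the sources used here. Libraries were made from 500 ng of RNA with a stranded mRNA kit and sequenced as pairs of 125 bases, per the labels' protocols, whereas the series' design text describes ribosomal RNA depletion and 2 cultures per group. The sample labels and the deposited table both hold 3 libraries per group, and these were used.

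The authors deposited 1 table of raw read counts, whole numbers for 31998 Ensembl rat gene identifiers in 6 libraries. Trimmomatic 0.39, STAR 2.7.1a, Salmon 0.14.1, featureCounts, DESeq2 and edgeR are named, without role or order, per the submitters' processing notes. Which tool produced the counts, whether strand was used in counting, the genome build and the annotation release are not given in the sources used here. Reads from overlapping or near-identical genes therefore cannot be assigned with certainty. Every column carried the title of 1 sample. No row lacked a gene identifier, and 11288 genes had no read in any library.

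The deposited table does not pair identifiers with gene names. The reference table used here, from assembly GRCr8 with 47357 genes, carries no Ensembl identifiers, and 0 of the 31998 identifiers matched it. Gene names, coordinates, gene length and GC content were therefore not used here. The 36 gene lists that were fixed before the data were examined (lipid metabolism, stress, inflammation, synapse and cell type markers) were written as symbols and could not be tested. The rule for named genes, fixed at the same time, required a symbol and so selected none. The 4 identifiers described in detail were chosen after their values were seen. They are the 2 higher genes called by the paired DESeq2 fit, the lower gene with its smallest adjusted p, and the lower gene among its calls with the smallest unpaired edgeR p.

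Computation was done in R 4.3.3. The main test was edgeR 4.0.16 (quasi-likelihood F test on counts, TMM scaling, filterByExpr with a minimum count of 10, treatment as the only term, all 6 libraries), with Benjamini-Hochberg adjustment over 13938 genes and a threshold of 0.05. The standard error of an edgeR log2 fold change was taken as its size divided by the square root of F. Group levels are CPM values on TMM-scaled totals, as mean ± SD over 3 libraries. Principal components and the changes within specimens over all genes used log2 CPM with a prior count of 2. Log2 ratios of a printed gene within a specimen used CPM with no prior count, and a ratio over 1 to 3 reads is given with its exact Clopper-Pearson interval. Alternatives were the DESeq2 1.42.0 Wald test, limma 3.58.1 with voom, DESeq2 size factors in edgeR, no filter, a filter of 1 CPM in 3 libraries, an added log2 fold threshold of 1, the specimen number as a block, and leaving out each library or specimen. The limma fit with a block and the blocked fits without a specimen were added after the data were seen.

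The specimen labels 1, 4 and 5 each occur once per treatment, so they pair the libraries. The deviations of same-numbered libraries from their group means correlated at 0.771, 0.89 and 0.855 across genes. The labels do not say how many animals make up a specimen. The p-values of the unpaired fits measure the spread between these cultures. With the specimen as a block, they measure how the treatment difference varies between specimens, with 2 residual degrees of freedom for a gene taken alone. The edgeR, limma and DESeq2 fits also share information on spread across genes. A small p-value of a gene therefore does not rest on its own specimens alone. No 2 libraries were copies. Over genes with at least 10 reads, the chi-square statistic per degree of freedom was 46.6 or more for libraries of the same group and 7.94 or more for any pair, where sampling noise alone gives about 1.

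Library totals ran from 15875411 to 18241773 counts. A gene with 0 reads in a library can have had up to 3 reads, or 0.164 to 0.189 CPM, and this limit covers counting error only. Each fit was tested on simulated data built from the specimen means and paired dispersions of these libraries, over 13938 genes with 200 changed genes. For palmitic acid against vehicle, the unpaired edgeR fit recovered 0 of 66 genes changed 4-fold and 0 of 67 changed 2-fold, as did the unpaired limma fit. The unpaired DESeq2 fit recovered 48 of 66 (72.7%) and 16 of 67 (23.9%), with 1 false call. The paired edgeR fit recovered 98.5% of genes changed 4-fold, 73.1% of those changed 2-fold and 14.9% of those changed 1.5-fold, with 23 false calls. The paired DESeq2 fit recovered 98.5%, 68.7% and 22.4%, with 23 false calls. With specimen differences left out of the simulation, the unpaired edgeR fit recovered 100% of genes changed 4-fold and 64.2% of those changed 2-fold, with 16 false calls.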

Results

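RNA was sequenced from 6 primary rat hippocampal neuron cultures, 3 given vehicle and 3 given 200 µM palmitic acid, a saturated fatty acid. Each of the specimens labelled 1, 4 and 5 gave 1 culture to each treatment. The vehicle libraries held 16536568, 15875411 and 17511122 counts for specimens 1, 4 and 5, and the palmitic acid libraries held 17601699, 17697819 and 18241773. Between 17213 and 17940 genes had at least 1 read in a library. The 10 genes with most reads took 6.29% to 9.02% of the counts in the libraries of specimens 1 and 5, and 10.7% to 11.7% in those of specimen 4. The deposited table identifies genes by Ensembl identifier without names, so genes are given by identifier, and groups of genes by expression pattern.

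The libraries were set apart by specimen more than by treatment. The first principal component of log2 CPM held 79.5% of the variance, and placed the specimen 4 libraries at 109.7 (vehicle) and 114.5 (palmitic acid). The other 4 libraries lay between -64.6 and -50. The second component held 10.5% of the variance, with the specimen 1 libraries at -31 and -38.6 and the specimen 5 libraries at 30.9 and 35.2. Vehicle and palmitic acid libraries of a specimen correlated at 0.983, 0.974 and 0.988 in log2 CPM for specimens 1, 4 and 5. The vehicle libraries of specimens 1 and 5 correlated at 0.966, and that of specimen 4 correlated with them at 0.857 and 0.832.

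**Figure D1:**
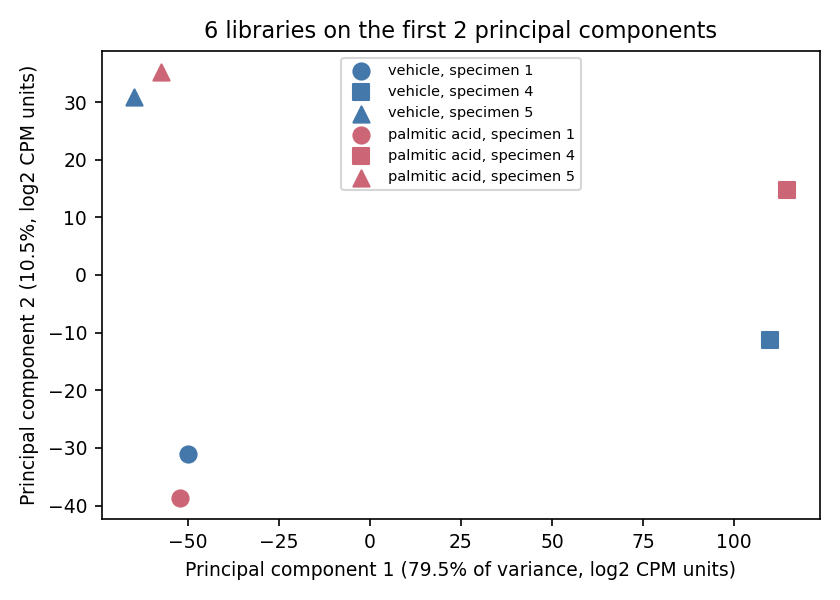
Each point is 1 library, placed by its first (x axis) and second (y axis) principal components of log2 CPM; colour gives the treatment and shape the specimen. The specimen 4 libraries lie at 109.7 and 114.5 on the first component, and all others between -64.6 and -50.

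With treatment as a covariate, edgeR's quasi-likelihood test separated specimen 4 from specimen 1 at 4528 of 13938 genes (Benjamini-Hochberg adjusted p under 0.05), of which 1867 were higher and 2661 lower in specimen 4. Specimen 5 differed from specimen 4 at 4830 genes, 2879 higher and 1951 lower in specimen 5. Specimens 5 and 1 differed at 407 genes, 314 higher and 93 lower in specimen 5. Each specimen enters with 2 libraries, 1 per treatment. These p-values are set against the spread left after specimen and treatment, so the counts describe these cultures only. A group of 144 genes stood at 10 CPM or more in all 4 libraries of specimens 1 and 5 and under 1 CPM in both libraries of specimen 4. These genes made up 0.978% of the counts in the 4 libraries that held them. The same criterion gave 1 gene for specimen 1 and 0 for specimen 5.

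The main comparison, palmitic acid against vehicle, asks which transcripts the fatty acid changes in neurons. No gene passed the unpaired edgeR test (0 higher and 0 lower of 13938, smallest adjusted p = 1). At an unadjusted p under 0.05 there were 29 higher and 11 lower genes, 40 in all, against 697 for a uniform spread of p-values. The unpaired DESeq2 and limma fits also called 0 genes, with 84 and 38 at an unadjusted p under 0.05. On simulated data with the specimen differences of these libraries, the unpaired edgeR and limma tests recovered 0 of 66 genes changed 4-fold, so a change of that size was not detectable by them here. The unpaired DESeq2 fit recovered 48 of those 66 genes (72.7%) and 16 of 67 genes changed 2-fold (23.9%). That simulation had 13938 genes, against 20659 in the real fit, and held many changed genes, which eases the adjusted threshold for every gene. The real unpaired DESeq2 fit did not call ENSRNOG00000007545 (log2 fold change 1.87) or ENSRNOG00000020009 (2.2). Its simulated recovery therefore does not show how often it would find a 4-fold change here.

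With the specimen as a block, the edgeR biological coefficient of variation went from 0.503 to 0.171, and the median standard error of a log2 fold change from 0.317 to 0.169. The paired edgeR test still called 0 genes (smallest adjusted p = 0.279). At an unadjusted p under 0.05 it had 280 higher and 213 lower genes, 493 in all, against 697 for a uniform spread of p-values. The paired limma fit called 0 genes, with 557 at an unadjusted p under 0.05, also against 697. The paired DESeq2 fit called 6 genes of 20710, 2 higher and 4 lower with palmitic acid. It had 399 genes at an unadjusted p under 0.05, against 1036 for a uniform spread. This fit had no filter on low counts, unlike the edgeR and limma fits. Its genes include many with too few reads to reach a small p, so a uniform spread is not a fair reference for it. ENSRNOG00000007219 and ENSRNOG00000017496 were lower calls not detailed below. The first had 321 ± 134 CPM with vehicle and 188 ± 76.9 with palmitic acid, adjusted p = 0.00425. The second had 210 ± 154 and 137 ± 101 CPM, adjusted p = 0.0278. Their log2 ratios in specimens 1, 4 and 5 were -0.84, -0.52 and -0.97, and -0.62, -0.66 and -0.61. Paired edgeR gave both an adjusted p of 0.938. Swapping the treatments within specimens gave 1, 2 and 4 calls in the paired DESeq2 fit. On simulated data the paired DESeq2 and edgeR fits each made 23 false calls, more than the threshold allows for, and each recovered 98.5% of genes changed 4-fold. Those data held many changed genes, which eases the adjusted threshold for every gene. The real paired edgeR fit gave ENSRNOG00000007545 a log2 fold change of 1.9 with unadjusted p = 2e-05, yet an adjusted p of 0.279. The simulated recovery therefore does not show how often the paired fits would find a 4-fold change here.

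ENSRNOG00000007545 had more reads with palmitic acid in 3 of 3 specimens and had the smallest adjusted p in the paired DESeq2 fit (log2 fold change 1.88 ± 0.27 SE, 3.69-fold, adjusted p = 6.91e-08). Its reads went from 161 to 702 in specimen 1, from 2 to 7 in specimen 4 and from 333 to 1210 in specimen 5. Its level was 9.61 ± 9.46 CPM with vehicle and 35.5 ± 33.1 CPM with palmitic acid (SD, n = 3), and the groups overlapped. The log2 ratio of CPM was 2.05 in specimen 1 and 1.8 in specimen 5. In specimen 4 the ratio of 7 to 2 reads was 2.98 after scaling, with an exact 95% counting interval of 0.567 to 29.4, so no difference was shown there. The paired edgeR fit gave 1.9 ± 0.17 (SE), adjusted p = 0.279, and the unpaired fit 1.88 ± 1.78, adjusted p = 1. The paired DESeq2 log2 fold change was 1.92 without specimen 4 (adjusted p = 2.23e-10), 1.76 without specimen 1 (adjusted p = 0.206) and 1.94 without specimen 5 (adjusted p = 1), so the last 2 lost the call at a similar fold. Paired edgeR without specimen 4 also called it (1.92, adjusted p = 0.0273). That fit left out the pair with few reads and rests on specimens 1 and 5 only, so it is no added support.

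ENSRNOG00000020009, the other higher gene, went from 15 to 103 reads in specimen 1, from 187 to 1503 in specimen 4 and from 151 to 212 in specimen 5. The paired DESeq2 log2 fold change was 1.94 ± 0.42 (SE), adjusted p = 0.0222, while paired edgeR gave an adjusted p of 0.938. Its level was 7.22 ± 5.75 CPM with vehicle and 33.5 ± 43 CPM with palmitic acid (SD, n = 3). The unpaired log2 fold change of 2.21 became 0.25 without the palmitic acid library of specimen 4 and 0.87 without both of its libraries. The paired DESeq2 log2 fold change was 2.73 without specimen 5 (adjusted p = 5.41e-08), 1.6 without specimen 1 (adjusted p = 0.4) and 1.46 without specimen 4 (adjusted p = 1). Paired edgeR without specimen 5 also called it (2.73, adjusted p = 0.000627). The log2 ratio was 0.42 in specimen 5, against 2.71 in specimen 1 and 2.77 in specimen 4. Leaving out specimen 5 thus removed the pair that differed from the others, and the call is no added support.

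ENSRNOG00000009345 was lower in 3 of 3 specimens, from 988 to 277 reads in specimen 1, from 133 to 62 in specimen 4 and from 1469 to 884 in specimen 5. The paired DESeq2 log2 fold change was -1.36 ± 0.26 (SE), adjusted p = 0.00152, and paired edgeR gave -1.34 ± 0.23, adjusted p = 0.938. The level was 50.6 ± 38.4 CPM with vehicle and 22.5 ± 23.2 CPM with palmitic acid (SD, n = 3). The paired DESeq2 log2 fold change was -1.35 without specimen 4 (adjusted p = 0.0013), -1.04 without specimen 1 (adjusted p = 0.518) and -1.66 without specimen 5 (adjusted p = 0.0582).

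ENSRNOG00000047104 had 27, 13 and 24 reads in the vehicle libraries of specimens 1, 4 and 5 and 0 in every palmitic acid library. Had the palmitic acid group held a limit of 3 reads in place of 0, the 64 vehicle reads would put this gene 23.2-fold lower after scaling. That value leaves out counting error in the vehicle reads and the spread between cultures. The gene's adjusted p was 0.0467 in the paired DESeq2 fit, 0.08 in the paired limma fit and 0.113 in the unpaired DESeq2 fit. It was 0.938 in the paired edgeR fit and 1 in the unpaired edgeR fit. The paired DESeq2 call was lost without any 1 of specimens 1, 4 and 5 (log2 fold change -6.75, -7.19 and -6.85 with adjusted p = 1, 0.399 and 1, against -6.93 over all specimens). These fitted values depend on how 0 reads are treated and are no bound.

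**Figure D2:**
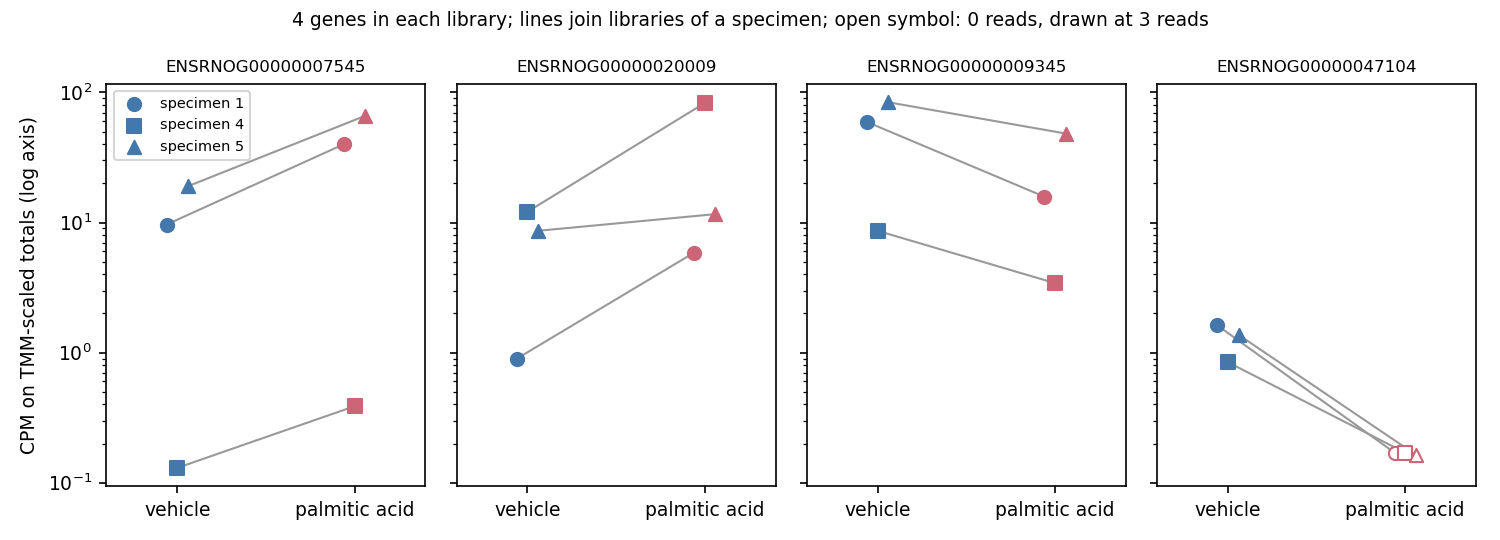
CPM on TMM-scaled totals (y axis, log scale) of the 4 genes described in detail, in each library, by treatment (x axis). Symbols give the specimen, lines join the 2 libraries of a specimen, and open symbols mark 0 reads, drawn at 3 reads. Both libraries of every specimen differ in the same direction for each gene, though ENSRNOG00000007545 in specimen 4 rests on 2 and 7 reads, and levels differ widely between specimens.

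The differences between the palmitic acid and vehicle libraries of a specimen correlated weakly between specimens. Each difference rests on 1 library per treatment, so an unshared response cannot be told apart from a shared one that is small or limited to few genes. Across 13938 genes, the log2 change of specimen 1 correlated with that of specimen 4 at r = -0.03 (Spearman's rho -0.06) and with that of specimen 5 at r = 0.1 (rho 0.09), and specimens 4 and 5 correlated at r = 0.1 (rho 0.14). These are correlations across genes, which are not independent replicates. Among 5867 genes with a mean log2 CPM of at least 5, the values of r were -0.11, 0.08 and 0.21 for the same pairs of specimens. All 3 specimens moved the same way at 26.5% of genes, 2197 higher and 1500 lower, where independent signs give 25%. A change of over 2-fold in all 3 specimens was seen at 7 genes higher and 1 lower with palmitic acid. This count was not made with the treatments swapped, so it cannot be set against chance. The groups did not overlap at 463 genes (3.32%), 304 higher and 159 lower. Exchangeable libraries would give 10% by chance, which does not apply to libraries paired by specimen. Swapping the treatments within specimen 4, within specimen 5 or within both gave 368, 274 and 378 such genes (2.64%, 1.97% and 2.71%).

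The size of the change differed between specimens. The SD of log2 changes across genes was 0.45 in specimen 1, 0.62 in specimen 4 and 0.36 in specimen 5, and 0.28, 0.43 and 0.15 among the genes with a mean log2 CPM of at least 5. Palmitic acid and vehicle differed by over 2-fold at 412 genes in specimen 1, 988 in specimen 4 and 211 in specimen 5. Each specimen has 1 culture per treatment, so these spreads carry no replicate check.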

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

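The unpaired counts of 0 higher and 0 lower genes were also 0 under DESeq2, limma and DESeq2 size factors in edgeR. They stayed 0 with either other filter, the added log2 threshold of 1, and any 1 library or any 1 specimen left out. On simulated data the unpaired edgeR and limma fits recovered no changed gene, so their zeros say nothing of stability. Unpaired DESeq2 recovered 72.7% of genes changed 4-fold among 13938 simulated genes. Those data held many changed genes, which eases the adjusted threshold. The real unpaired DESeq2 fit had 20659 genes, and gave ENSRNOG00000007545 and ENSRNOG00000020009 an adjusted p of 1. The 72.7% therefore does not show how often that fit would find a 4-fold change here, and its zeros are no evidence of stability. The replicate block kept 0 and 0 in edgeR and limma, and gave 2 higher and 4 lower in DESeq2. Blocked fits without a specimen were chosen after seeing the data. They have fewer residual degrees of freedom than the 2 of the full blocked fit, so their p-values lean more on spread shared across genes. In edgeR they called 2 higher and 4 lower genes without specimen 1, 3 and 1 without specimen 4, and 4 and 1 without specimen 5. In DESeq2 they called 2 higher and 3 lower without specimen 1, 3 and 8 without specimen 4, and 6 and 0 without specimen 5. Of the 6 genes of the full paired DESeq2 fit, 0 remained called without specimen 1, 4 without specimen 4 and 1 without specimen 5; the cause was not tested. None of the 4 genes described in detail changed direction in any alternative. They were chosen from calls on these same libraries and differed in the same direction in every specimen, so this was largely set by the choice. ENSRNOG00000007545 ranged from 1.07 to 2.81 (log2) and passed in 3 of 23 alternatives, ENSRNOG00000020009 from 0.25 to 2.82 in 3 of 23, ENSRNOG00000009345 from -2.4 to -0.64 in 2 of 23, and ENSRNOG00000047104 from -7.73 to -5.52 in 1 of 22. ENSRNOG00000047104 did not pass the filter of 1 CPM in 3 libraries, so it had no value under that alternative. The unpaired edgeR and limma alternatives could hardly call any gene, and the passes include the paired DESeq2 fit that chose these genes. The counts of passes are therefore neither a failure rate nor independent support. The other size factors shifted the median log2 fold change by -0.016. The gene list tests and their alternatives were not run, because the identifiers could not be paired with symbols.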

Other observations

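The thinning of libraries, the removal of the 100 genes of most reads and the swaps of treatment within specimens were set before their results were seen, and the other tests here were chosen after. The specimen 4 libraries stood apart from the other 4 on the first principal component, by 10.9 times the range of those 4. Thinning all libraries to the smallest total left 79.3% of the variance on that component, against 79.5%, and removing the 100 genes left 79.4%, but the totals are close and every library is scaled, so neither test was able to move the pattern much and neither is counted. Depth is argued against by the totals themselves. The vehicle library of specimen 4 held 15875411 counts, fewer than any other library, while its palmitic acid library held 17697819, within the 16536568 to 18241773 counts of the other 4 libraries, and the pair lay together on the component at 109.7 and 114.5. A few dominant genes are argued against as well: the 100 genes of most reads took 20.4% to 24.7% of the counts, a difference that could shift all other genes by at most 0.081 on the log2 scale, while 377 genes differed by over 32-fold between specimens 4 and 1. Of those 377 genes, 366 were lower in specimen 4. All 4528 genes called for specimen 4 against 1 leaned the same way less strongly, with 1867 higher and 2661 lower in specimen 4. Other sizes of difference were not examined. There were 144 genes near absent from specimen 4, against 1 and 0 for specimens 1 and 5. The reverse criterion gave 0 genes for specimen 4, against 0 and 4 for specimens 1 and 5. A candidate explanation is that the specimen 4 cultures had another cell makeup, lacking cells that the others held, but it cannot be told apart from a difference in animals, dissection or culture day, because testing cell type markers needs gene names.

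The calls were set against those of other splits of the 6 libraries, which are too few to show a share under 0.05. In the unpaired edgeR test, 10 of the 10 splits of the libraries gave as many genes as the real split, since the real value and the highest other were both 0. Of these splits, those that kept a specimen together had 426 to 1839 genes at an unadjusted p under 0.05, which points to the specimen structure, while the 4 that parted all 3 pairs had 40 (the real one), 8, 10 and 22. In the paired DESeq2 fit, 1 of the 4 splits that part all pairs gave as many calls, with 6 genes in the real split and 4 in the highest other. The paired edgeR fit had 493 genes at an unadjusted p under 0.05 in the real split, and 523 in the highest other.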
